A study of Pseudomonas putida KT2440 with 30 samples.

How the data were processed

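RNA-seq was measured in 30 libraries of Pseudomonas putida KT2440, in 10 groups of 3: cultures without addition, with stable FeCl3, with Pu-239, with H-3 and with Fe-55, each on day 1 and day 15. Per the labels' protocols, cultures grew in M9 medium with glucose and casamino acids, rRNA was depleted with 1 of 2 kits (Ribo-Zero or RiboMinus, without saying which library had which), and libraries were made with a stranded kit. Per the submitters' processing notes, reads were trimmed with Trim Galore 0.6.5, mapped with HISAT2 2.2.1, sorted with SAMtools 1.4 and assigned to genes with StringTie 1.3.3b, and the authors' own tests used DESeq2 1.35.0. The deposited table gives for each gene and library an estimated count, an FPKM value and a length. The estimated counts are fractional in the deposited table: 0.28% of them were whole numbers within 1e-06. The deposited FPKM values were not tested: in every library the ratio of estimated count to FPKM and length was constant across genes. The genome build is not given in the sources used here, and no coordinates are printed.

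The table has 5785 entries, of which 2080 carry a gene symbol, 3540 a locus tag, and 919 symbols were found in the reference annotation of the strain. Symbols carry a suffix such as -I or -II for copies, whose reads can be split between copies. The 98 entries of rRNA (22), tRNA (75) and tmRNA (1) were left out of the tests, and 5687 were kept, including 67 PP_mr entries whose identity the files do not give. PP_mr entries took 2.99 ± 1.99% of all counts in H-3 day 1 and 17.6 ± 0.557% in Fe-55 day 15. No 2 libraries within a group were identical, with a chi-square per gene of at least 32.6 over the 30 pairs. The estimated counts were rounded and passed to edgeR 4.0.16 in R 4.3.3 (limma 3.58.1) with filterByExpr, TMM scaling, robust dispersion and the quasi-likelihood F test, and p was adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The common biological coefficient of variation was 0.287 on day 1, 0.239 on day 15 and 0.266 in all libraries. The 10 comparisons within a day and the 4 differences between sources used the 15 libraries of that day; the 2 comparisons between days and the 3 differences of effects between days used all 30. Summaries were made with Python 3.11.15 (numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9).

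The groups, tests, lists and the rule for named genes were fixed before the data were examined. The rule takes for each radionuclide, FeCl3 and time comparison the 8 largest rises and 8 largest falls with a symbol, an adjusted p under 0.05, a mean of at least 10 counts in the higher group and no overlap of the groups, up to 4 members of each list by p, the genes recA, lexA, recN, katE, ahpC, sodB, fur and rpoS in each radionuclide comparison, and the 4 smallest p in the other comparisons. For length the text names a part of these, chosen after their values were seen. Of all genes, 74 switch by at least 32-fold between replicates of a group, among them mutL, atoC, fliP, mlaE, capB, tapB, puuE, dppF, selU and lexA-II; the rule gave these 10 in some comparisons, but their folds are uncertain and are not given, and for lexA-II only abundances are. purN, which the rule also gave, was left out because it had near 0 CPM in all groups but those with FeCl3.

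Of 28 fixed lists, those for transposases, aminoacyl-tRNA synthetases and structural RNA had no members among the tested entries and were not run. The other 25 were pyoverdine synthesis, iron uptake and storage, SOS response and recombination, excision and mismatch repair, oxidative stress defence, ribosomal proteins, transcription and translation factors, ATP synthase, respiratory chain, tricarboxylic acid and glyoxylate cycle, glucose uptake and catabolism, flagella and chemotaxis, chaperones and proteases, stationary phase and general stress, polyhydroxyalkanoate metabolism, efflux pumps, metal resistance, amino acid catabolism, type VI secretion, biofilm and exopolysaccharide, nitrogen, phosphate and sulfur limitation or assimilation, prophages, and cell division and peptidoglycan. Each was tested with camera at a preset correlation of 0.01 and again with an estimated correlation. The second test kept fewer calls.

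The tests were tried on simulated data: negative binomial counts with 1 mean profile for all groups and the fitted dispersions, in which 100 genes changed 2-fold and 100 changed 4-fold, up or down. At 4-fold, 93% were recovered for Pu-239 on day 1 and 97% on day 15, and at 2-fold 49% and 69%. For the difference of the Pu-239 effect between days, 77% were recovered at 4-fold and 23% at 2-fold. Between 5 and 10 of 5438 to 5455 unchanged genes were called. The changed genes were drawn from the more abundant ones, and most genes were left unchanged. These rates need not hold for genes of low count or for comparisons in which most genes differ. Whether replicate numbers pair the libraries was checked on deviations from group means: those of H-3 and Fe-55 on day 1 correlated by number across genes (r = 0.47, 0.292 and 0.587, and -0.212 on average for other numbers), those of other groups did not rise above 0.158. Control and Pu-239 on day 1 gave 0.076, 0.158 and 0.117, and -0.054 on average for other numbers. The tests treat the libraries as independent.

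Alternatives fixed beforehand were DESeq2 1.42.0 in place of edgeR, RLE scaling, no filter, structural RNA kept in, a minimum of 2-fold, a replicate block, fits of the 6 libraries or of all 30, the culture without addition as control for Fe-55, each replicate left out in turn, and camera with an estimated correlation or fry. Chosen after seeing the data were leaving out libraries over 30% rRNA, the PP_mr entries or the switching genes, the culture without addition as control in the differences of Fe-55, and Fe-55 against H-3 directly.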

Results

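The series holds 30 RNA-seq libraries of Pseudomonas putida KT2440, a soil bacterium, in 10 groups of 3 replicates. Cultures were kept for 1 or 15 days with a dissolved radionuclide, each set to give 9 mGy per day per the labels: Pu-239, an alpha emitter, H-3 as tritium, a weak beta emitter, or Fe-55, which decays by electron capture. Cultures without any addition were the control for Pu-239 and H-3, and cultures with 2.47 µM stable FeCl3 were the chemical control for Fe-55. Activities were 0.12 kBq/mL for Pu-239, 3 µCi/mL for H-3 and 4.9 µCi/mL for Fe-55. The labels give an HCl stock of 0.01 M for Pu-239 and 0.5 M for Fe-55, and none for the other groups. Acid added with these stocks cannot be told apart from the radionuclide. The labels do not say that the replicates came from separate cultures. Estimated counts per library ranged from 12.7 M (FeCl3 day 15, replicate 2) to 189.7 M (H-3 day 15, replicate 2). Of these, genes outside rRNA, tRNA and tmRNA held 4.08 M (H-3 day 15, replicate 3) to 109.05 M (H-3 day 1, replicate 3). rRNA took 81.4% of the counts of replicate 2 of the day 1 control, 78.0% of H-3 day 1 replicate 1, 77% of H-3 day 15 replicate 3 and 34.8% of Pu-239 day 1 replicate 3. Values in parentheses after a gene are its log2 fold change ± standard error with 3 replicates per group, and abundances are CPM from edgeR with TMM scaling ± SD with n = 3. Each gene named as higher or lower between 2 groups had all 3 libraries of one group above all 3 of the other, except where the text says otherwise. Counts of list members are of genes called among all genes, and counts over the list alone follow where they differ. After them stands the adjusted p of camera with a preset correlation and, where that is under 0.05, the one with an estimated correlation.

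The libraries formed 2 sets along the main axis of variation, and the sets did not follow radiation. On the first principal component, which carried 58.8% of the variance, the cultures without addition and with Pu-239 on both days and those with H-3 and Fe-55 on day 1 lay between 11.2 and 82.0. The FeCl3 cultures of both days and the H-3 and Fe-55 cultures of day 15 lay between -110.2 and -48.7. tmRNA, the RNA that rescues stalled ribosomes, took 29.5 ± 5.94% of the counts outside rRNA in FeCl3 day 1 and 47.6 ± 1.33% in FeCl3 day 15. Its share was 44.3 ± 4.25% in H-3 day 15 and 42.9 ± 8.45% in Fe-55 day 15, and 16.9 ± 1.33% in the control of day 15. On day 1 it was 8.39 ± 0.188% in the control, 7.81 ± 1.28% with Pu-239, 6.86 ± 1.73% with H-3 and 11.9 ± 2.15% with Fe-55. The FeCl3 cultures of day 1 had a mean correlation across genes of 0.831 with those of day 15 and of 0.548 to 0.563 with the other groups of day 1.

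**Figure D1:**
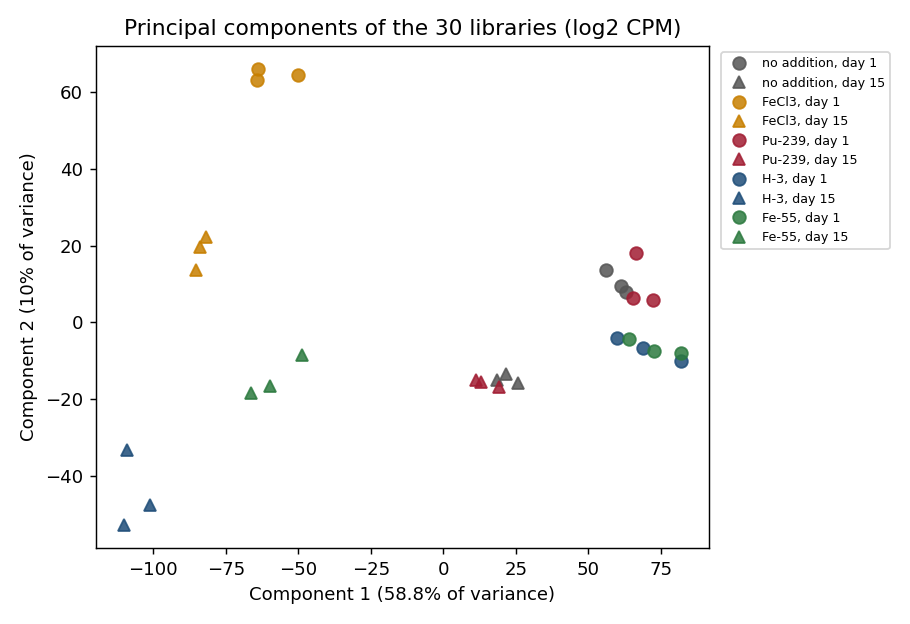
Scores of the 30 libraries on the first and second principal components of log2 CPM, one point per library, with colour for the treatment and shape for the day. The FeCl3 libraries of both days and the H-3 and Fe-55 libraries of day 15 lie at -48.7 or below on component 1, and all others at 11.2 or above.

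**Figure D2:**
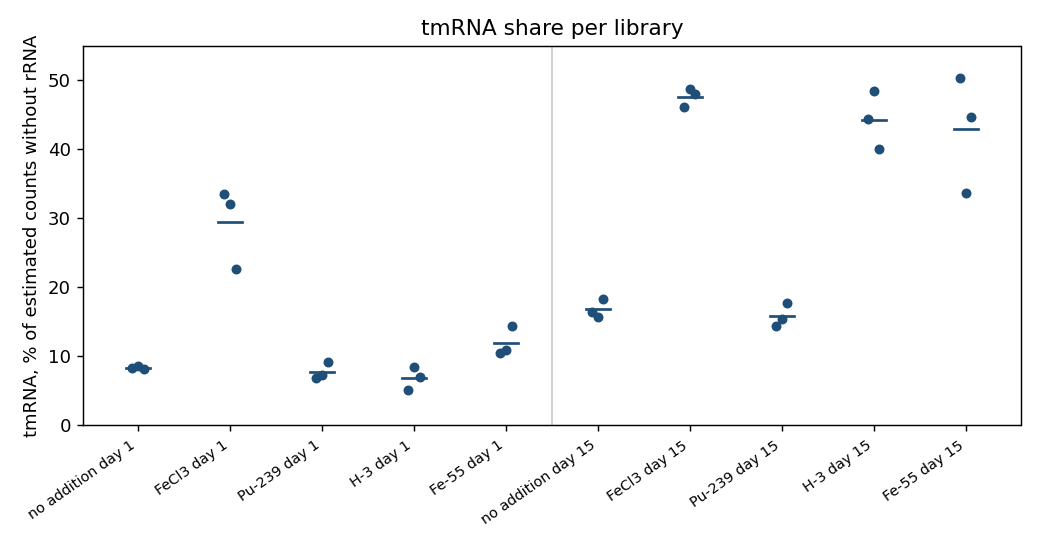
Share of tmRNA in the estimated counts outside rRNA, in percent, with one point per library and a bar for the mean of each group. The means run from 6.86% with H-3 on day 1 to 47.6% with FeCl3 on day 15.

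Pu-239 against the culture without addition on day 1 asked what an alpha emitter at a low dose rate does to young cultures. Genes for pyoverdine, the fluorescent siderophore that gathers iron, were far lower with Pu-239: all 16 tested members fell, with a median log2 fold change of -3.84. Among them were pvdM (-5.15 ± 0.25), pvdA (-5.00 ± 0.19) and pvdI (-4.62 ± 0.20, adjusted p of each at most 3.65e-09). The pyoverdine receptor gene fpvA (-2.85 ± 0.17, adjusted p = 4.88e-08) and the manganese superoxide dismutase gene sodA (-4.38 ± 0.39, adjusted p = 1.87e-06) fell with them. The abundance of pvdA was 342 ± 30.2 CPM in the control and 10.7 ± 0.926 CPM with Pu-239. Among the genes with a symbol that rose were syrB (6.52 ± 0.33, adjusted p = 4.65e-09), the tryptophan synthase genes trpB (4.79 ± 0.21) and trpA (4.05 ± 0.20, adjusted p of each at most 4.14e-09), the aminotransferase gene aspC (4.25 ± 0.14, adjusted p = 4.66e-10) and the S-adenosylmethionine synthetase gene metK (3.79 ± 0.34, adjusted p = 1.73e-06).

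Of the pyoverdine list, 16 of 16 tested members were lower and none higher (camera adjusted p = 2.23e-67 and 1.19e-06). Respiratory genes were higher, among them the cyanide-insensitive oxidase genes cioB (3.16 ± 0.27) and cioA (2.42 ± 0.30, adjusted p of each at most 4.22e-05) and the NADH dehydrogenase gene nuoL (1.42 ± 0.17, adjusted p = 3.77e-05). In that list 15 of 36 tested members were higher and none lower, 16 and 0 over the list alone (camera adjusted p = 1.46e-05 and 0.577). Genes of nitrogen limitation included glutamine synthetase, glnA (1.84 ± 0.25, adjusted p = 8.65e-05), and the ammonium transporter, amtB (2.10 ± 0.39, adjusted p = 0.00118): 12 of 25 tested members were higher and none lower, 15 and 1 over the list alone (camera adjusted p = 0.0028 and 0.132). Of cell division and peptidoglycan genes, 15 of 39 tested members were higher and none lower (camera adjusted p = 0.000423 and 0.577), with ftsA (1.79 ± 0.25) and ftsZ (1.80 ± 0.28, adjusted p of each at most 0.000324). Of the list of glucose uptake and catabolism, 11 of 32 tested members were higher and none lower, 11 and 1 over the list alone (camera adjusted p = 0.036 and 0.577), among them zwfA (1.94 ± 0.18) and pgl (1.96 ± 0.20, adjusted p of each at most 6.94e-06). Lower groups were flagella and chemotaxis, prophages and iron uptake. Of flagella and chemotaxis, 14 of 46 tested members were lower and none higher, 16 and 0 over the list alone (camera adjusted p = 0.00529 and 0.577), as for the rod and hook genes flgD (-1.14 ± 0.19) and flgE (-1.16 ± 0.26, adjusted p of each at most 0.00517). Of prophage genes, 3 of 185 tested members were higher and 33 lower, 3 and 29 over the list alone (camera adjusted p = 0.00042 and 0.577). Of iron uptake and storage, 5 of 11 tested members were lower and none higher, 6 and 0 over the list alone (camera adjusted p = 0.00529 and 0.148). Of the list of efflux pumps, 1 of 14 tested members were higher and 4 lower (camera adjusted p = 0.036 and 0.577), with mexF (-2.27 ± 0.25) and oprN (-2.41 ± 0.27, adjusted p of each at most 1.38e-05) lower.

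Of SOS response and recombination, 6 of 26 tested members were higher and none lower (camera adjusted p = 0.0783), with the repressor gene lexA-I (1.08 ± 0.14, adjusted p = 6.03e-05) higher. The recombinase gene recA (0.25 ± 0.19, adjusted p = 0.367), whose product sets off the SOS response, and the break repair gene recN (0.13 ± 0.16, adjusted p = 0.6) did not pass. Of excision and mismatch repair, 6 of 20 tested members were higher and none lower, 6 and 1 over the list alone (camera adjusted p = 0.237), among them uvrB (0.75 ± 0.14, adjusted p = 0.00119). Of oxidative stress defence, 3 of 26 tested members were higher and 3 lower (camera adjusted p = 0.988), with a median of 0.11 and a mean of -0.06. Here sodA fell, while sodB (1.07 ± 0.21, adjusted p = 0.00217) rose. ahpC (0.77 ± 0.20, adjusted p = 0.0119) was higher but did not pass without replicate 2 of the control (adjusted p = 0.058) or replicate 3 of Pu-239 (0.0541). The catalase gene katE (-0.25 ± 0.18, adjusted p = 0.334) and the iron regulator gene fur (0.29 ± 0.17, adjusted p = 0.226) did not pass. rpoS (0.93 ± 0.29, adjusted p = 0.0297) was higher, but did not pass when any 1 of the 3 control libraries or replicate 1 or 3 of Pu-239 was left out (adjusted p from 0.0559 to 0.109). Nor did ahpC (0.134) or rpoS (0.193) pass without the libraries over 30% rRNA, or ahpC in a fit of all 30 libraries (0.0617). Of the 5647 genes tested, 1375 passed (edgeR quasi-likelihood test), 707 higher and 668 lower. A fit of the 6 libraries alone called 2105, and the count was 1129 without the libraries over 30% rRNA, an alternative chosen after seeing the data.

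Pu-239 against control on day 15 asked the same of old cultures. Genes of respiration and energy were among those lower with Pu-239, though their lists did not pass with an estimated correlation. The cbb3-type oxidase genes ccoN-I (-2.83 ± 0.18) and ccoO-I (-2.82 ± 0.24, adjusted p of each at most 1.71e-06), the oxidase gene cioA (-2.83 ± 0.21, adjusted p = 4.02e-07) and the lactate dehydrogenase and permease genes lldD (-2.81 ± 0.22) and lldP (-2.59 ± 0.18, adjusted p of each at most 7.79e-07) fell. With them fell cidB (-3.15 ± 0.39) and cidA (-3.14 ± 0.44, adjusted p of each at most 0.000408). The TonB system, which energises uptake through the outer membrane, rose: exbB (2.15 ± 0.24), exbD (2.01 ± 0.24) and tonB (1.73 ± 0.26, adjusted p of each at most 0.000291). The regulator genes gltR-I (2.45 ± 0.27) and oruR (1.99 ± 0.29, adjusted p of each at most 0.000229) and the iron-free fumarase gene fumC-I (1.95 ± 0.21, adjusted p = 1.7e-05) also rose. def-II stood at 62.3 ± 7.25 CPM with Pu-239 and 0.112 ± 0.0131 CPM in the control.

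Of the respiratory chain, 17 of 36 tested members were lower and none higher, 19 and 0 over the list alone (camera adjusted p = 4.58e-16 and 0.0965). Of ATP synthase, 7 of 9 tested members were lower and none higher, 8 and 0 over the list alone (camera adjusted p = 3.28e-08 and 0.0965), as for atpA (-1.41 ± 0.20) and atpG (-1.23 ± 0.18, adjusted p of each at most 0.000222). Of ribosomal proteins, 16 of 54 tested members were lower and none higher, 18 and 0 over the list alone (camera adjusted p = 3.42e-08 and 0.591), among them rpsC (-1.57 ± 0.27) and rplV (-1.45 ± 0.26, adjusted p of each at most 0.00106). Of chaperones and proteases, 1 of 21 tested members were higher and 10 lower, 1 and 11 over the list alone (camera adjusted p = 3.29e-05 and 0.442), with dnaK (-1.24 ± 0.16) and groL (-0.99 ± 0.17, adjusted p of each at most 0.000825) lower. Of amino acid catabolism, 4 of 45 tested members were higher and 18 lower, 6 and 20 over the list alone (camera adjusted p = 0.000113 and 0.304), with bkdB (-1.75 ± 0.25) and putA (-1.48 ± 0.22, adjusted p of each at most 0.000222) lower. Of transcription and translation factors, 6 of 22 tested members were lower and none higher, 7 and 0 over the list alone (camera adjusted p = 0.0119 and 0.667). Of pyoverdine synthesis, 1 of 16 tested members were higher and 8 lower, 1 and 11 over the list alone (camera adjusted p = 0.000504 and 0.442), where pvdH (-0.91 ± 0.20, adjusted p = 0.00442) fell and the sigma factor gene pvdS (1.28 ± 0.29, adjusted p = 0.00567) rose. Of iron uptake and storage, 6 of 11 tested members were higher and 3 lower (camera adjusted p = 0.045 and 0.55). Of the SOS list, 6 of 26 tested members were higher and 4 lower, 7 and 6 over the list alone (camera adjusted p = 0.54). recG (0.74 ± 0.15, adjusted p = 0.003) rose and recB (-1.26 ± 0.19, adjusted p = 0.000348) fell. recA (0.18 ± 0.19, adjusted p = 0.607) and lexA-I (-0.21 ± 0.19, adjusted p = 0.531) did not pass. The genes katE (0.04 ± 0.30, adjusted p = 0.961), ahpC (0.42 ± 0.35, adjusted p = 0.505), sodB (-0.00 ± 0.30, adjusted p = 0.999) and fur (0.04 ± 0.23, adjusted p = 0.947) did not pass either. recN (0.49 ± 0.15, adjusted p = 0.0318) and rpoS (0.73 ± 0.24, adjusted p = 0.0477) were higher, but did not pass when any 1 of the 6 libraries was left out (adjusted p from 0.0734 to 0.115 and from 0.052 to 0.192). Neither passed in a fit of all 30 libraries (0.0587 and 0.114) or without the PP_mr entries (0.097 and 0.122), nor rpoS with a replicate block (0.0542) or with structural RNA kept in (0.0517). lexA-I passed in a fit of the 6 libraries (0.0404).

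In total 988 of 5652 genes passed, 511 higher and 477 lower. Leaving the PP_mr entries out of the scaling, an alternative chosen after seeing the data, gave 286 higher and 497 lower, so the balance of rises and falls rests on the scaling. The SOS list then had only 2 higher and 4 lower, so most of its rises rest on the scaling too. The respiratory chain then had 0 higher and 18 lower, ATP synthase 0 and 7, ribosomal proteins 0 and 15, chaperones and proteases 0 and 11, amino acid catabolism 2 and 18, transcription and translation factors 0 and 5, pyoverdine synthesis 1 and 9, and iron uptake and storage 5 and 3. The count was 539 without replicate 3 of Pu-239, 581 without its replicate 2 and 550 without replicate 1 of the control, 2115 in a fit of the 6 libraries alone and 605 in a fit of all 30 libraries.

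**Figure D3:**
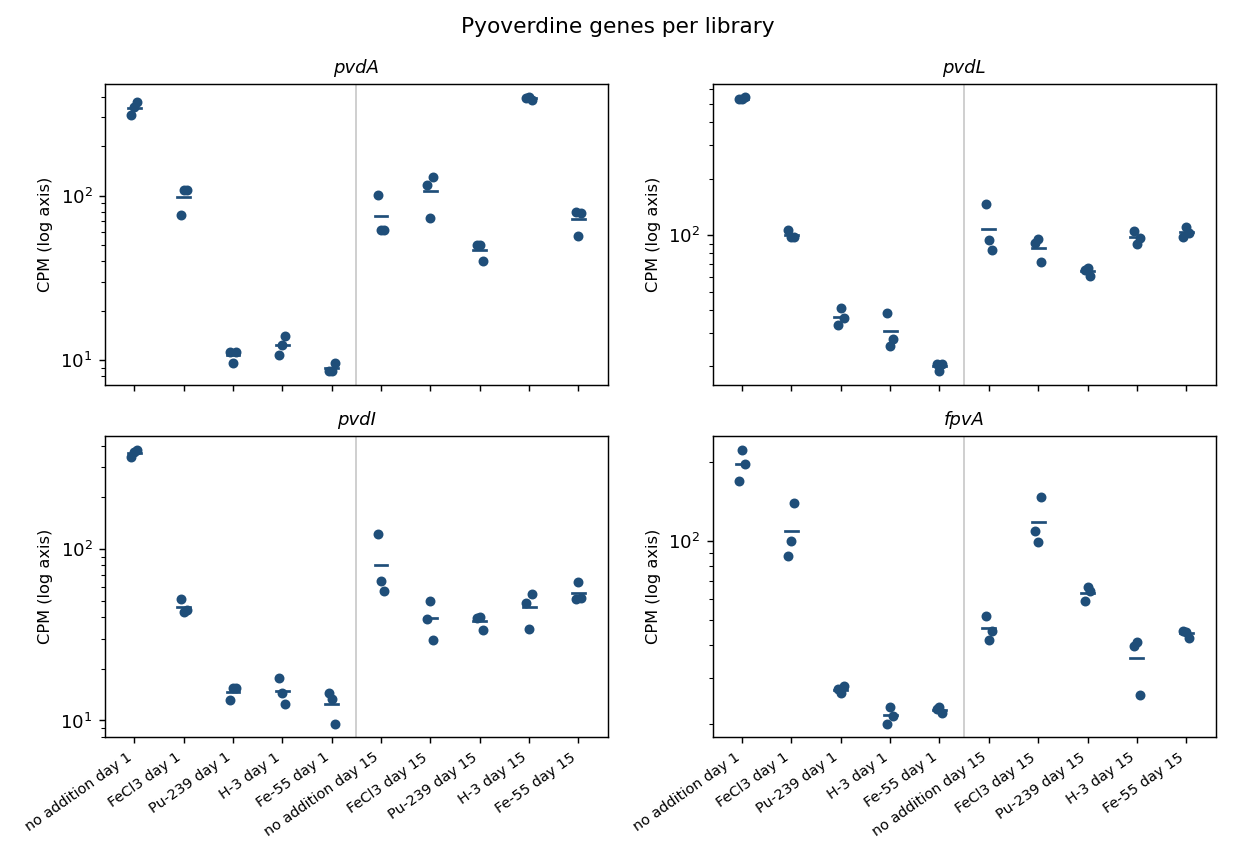
Abundance of the pyoverdine genes pvdA, pvdL and pvdI and of the receptor gene fpvA in CPM on a log axis, with one point per library and a bar for the mean of each group. pvdA lies between 309.6 and 369.5 CPM in the control of day 1, between 8.5 and 14.0 CPM with the 3 radionuclides on day 1, and between 382.6 and 395.7 CPM with H-3 on day 15.

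H-3 against control on day 1 asked what a weak beta emitter does to young cultures. Pyoverdine genes were lower with H-3 in all 16 tested members, with a median log2 fold change of -4.13, as for pvdM (-5.22 ± 0.25), pvdA (-4.78 ± 0.19) and pvdI (-4.62 ± 0.20, adjusted p of each at most 7.79e-09). The abundance of pvdA was 12.3 ± 1.66 CPM with H-3, 8.9 ± 0.581 CPM with Fe-55 and 97.5 ± 18.6 CPM with FeCl3 on the same day, so the control without addition, at 342 ± 30.2 CPM, had the highest level of that day. Flagellar genes were higher, among them the export gene flhA (3.15 ± 0.22, adjusted p = 2.14e-07), the sensor kinase gene fleS (3.01 ± 0.18, adjusted p = 5.41e-08) and fliO (2.94 ± 0.18, adjusted p = 8.22e-08). The chaperone genes groS (-2.53 ± 0.24), htpG (-2.35 ± 0.14) and dnaK (-2.37 ± 0.25, adjusted p of each at most 1.11e-05) were lower. So were the ketogluconate genes kguT (-3.89 ± 0.32), kguE (-3.26 ± 0.28) and kguK (-3.62 ± 0.33, adjusted p of each at most 3.48e-06). The phosphate uptake genes pstS (2.11 ± 0.20) and pstC (2.06 ± 0.21, adjusted p of each at most 7.55e-06) were higher.

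Of pyoverdine synthesis, 16 of 16 tested members were lower and none higher (camera adjusted p = 8.5e-68 and 4.52e-06). Of flagella and chemotaxis, 29 of 46 tested members were higher and 3 lower, 31 and 4 over the list alone (camera adjusted p = 2.11e-23 and 0.0964). Of chaperones and proteases, 9 of 21 tested members were lower and none higher, 10 and 3 over the list alone (camera adjusted p = 1.58e-05 and 0.29). Of phosphate limitation, 9 of 13 tested members were higher and none lower, 10 and 1 over the list alone (camera adjusted p = 5.3e-05 and 0.136). Of prophage genes, 2 of 185 tested members were higher and 53 lower, 2 and 51 over the list alone (camera adjusted p = 1.77e-06 and 0.434). Of iron uptake and storage, 1 of 11 tested members were higher and 5 lower (camera adjusted p = 0.0454 and 0.264), with fpvA (-3.17 ± 0.18) and hemO (-2.81 ± 0.31, adjusted p of each at most 2.02e-05) lower. Type VI secretion genes gave 0 members higher and 2 lower of 6 tested, 0 and 3 over the list alone (camera adjusted p = 0.0748), with vgrG-II (-1.21 ± 0.25, adjusted p = 0.00226) lower. In the SOS list 9 of 26 tested members were higher and 1 lower (camera adjusted p = 0.0521). recJ (0.95 ± 0.19, adjusted p = 0.00221) and lexA-I (0.59 ± 0.14, adjusted p = 0.00562) rose, and recA (0.55 ± 0.19, adjusted p = 0.0396) was higher and recN (-0.53 ± 0.16, adjusted p = 0.0236) lower. sodA (-4.83 ± 0.41, adjusted p = 1.55e-06) fell, katE (0.58 ± 0.18, adjusted p = 0.0233) was higher and ahpC (-0.73 ± 0.20, adjusted p = 0.013) lower. sodB (0.50 ± 0.21, adjusted p = 0.0847), fur (0.29 ± 0.17, adjusted p = 0.207) and rpoS (-0.78 ± 0.29, adjusted p = 0.0538) did not pass. recA passed only when replicate 3 of H-3 was the library left out (adjusted p from 0.0703 to 0.135 otherwise). recN did not pass without replicate 1 (0.071) or 3 (0.0695) of the control or replicate 2 of H-3 (0.0904). Nor did katE without the same 2 control libraries (0.0876 and 0.0657) or replicate 3 of H-3 (0.108), nor ahpC without replicate 1 of the control (0.0567). rpoS passed without replicate 3 of H-3 (0.0178), with a replicate block (0.00942), with DESeq2 (0.0367) and in a fit of all 30 libraries (0.0309). The block ended the call of recA (0.0612), and the fit of all 30 those of katE (0.0827) and ahpC (0.0642). sodB passed with DESeq2 (0.0329) and in a fit of the 6 libraries (0.0484), in which ahpC did not (0.0538). Without the libraries over 30% rRNA, recA (0.28) and recN (0.0668) did not pass. Of the 5647 genes tested, 1801 passed, 964 higher and 837 lower. Without the libraries over 30% rRNA, chosen after seeing the data, 547 were higher and 751 lower. The control libraries are the same as those of the Pu-239 comparison, so part of what both comparisons show can come from those libraries, and pvdA stood at 75 ± 22.7 CPM in the control of day 15.

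H-3 against control on day 15 asked the same of old cultures, and here most genes differed. Genes for making protein and energy were far lower: the median log2 fold change of ribosomal protein genes was -4.86 and that of ATP synthase genes -4.40. The FeCl3 cultures of this day, which had no radiation, were lower than the same control in both lists too. Among genes with a symbol, large falls were those of the urocanase gene hutU (-8.38 ± 0.40, adjusted p = 6.52e-11), the glucose-binding protein gene gtsA (-6.85 ± 0.33, adjusted p = 7.56e-11), the ribosomal protein gene rpmH (-6.69 ± 0.32, adjusted p = 6.52e-11), the chaperonin gene groS (-6.60 ± 0.20, adjusted p = 1.85e-12) and the cytochrome oxidase gene cyoB (-6.02 ± 0.32, adjusted p = 1.33e-10). Large rises were those of yohC (6.82 ± 0.37), sfsA (6.40 ± 0.81) and qmcA (6.26 ± 0.41, adjusted p of each at most 4.45e-06) and the acetoin regulator gene acoR (5.93 ± 0.31, adjusted p = 1.32e-10). The ribosome hibernation genes hpf (3.53 ± 0.24) and rmf (3.25 ± 0.28, adjusted p of each at most 1.84e-08) and the stationary phase sigma factor gene rpoS (2.03 ± 0.25, adjusted p = 1.35e-06) rose. tmRNA, at 44.3 ± 4.25% of the counts outside rRNA, moved with these groups.

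Of ribosomal proteins, 1 of 54 tested members were higher and 53 lower (camera adjusted p = 1.44e-27 and 0.332). Of ATP synthase, 9 of 9 tested members were lower and none higher (camera adjusted p = 1.1e-08 and 0.235). Of the respiratory chain, 3 of 36 tested members were higher and 29 lower (camera adjusted p = 2.72e-07 and 0.332). Of the tricarboxylic acid and glyoxylate cycle, 5 of 24 tested members were higher and 16 lower (camera adjusted p = 0.000496 and 0.369), with gltA (-3.52 ± 0.19) and idh (-3.72 ± 0.20, adjusted p of each at most 1.49e-10) lower. Of chaperones and proteases, 4 of 21 tested members were higher and 15 lower (camera adjusted p = 8.4e-06 and 0.369). Of transcription and translation factors, 1 of 22 tested members were higher and 20 lower (camera adjusted p = 3.9e-09 and 0.332). Of flagella and chemotaxis, 30 of 46 tested members were lower and none higher, 29 and 0 over the list alone (camera adjusted p = 0.0139 and 0.621), with the flagellin gene fliC (-2.62 ± 0.24, adjusted p = 4.71e-08) lower. Prophage genes went the other way, with 75 members higher and 18 lower of 184 tested, 74 and 18 over the list alone (camera adjusted p = 0.0343 and 0.762), as for PP_1540 (3.89 ± 0.24) and PP_1551 (4.38 ± 0.28, adjusted p of each at most 6.84e-10). Genes of metal resistance gave 15 members higher and 6 lower of 30 tested (camera adjusted p = 0.103), with the sensor and regulator genes czrSA (5.23 ± 0.34) and czcR-I (5.39 ± 0.38, adjusted p of each at most 1.65e-09) higher. Stationary phase and general stress gave 9 members higher and 8 lower of 20 tested, 9 and 9 over the list alone (camera adjusted p = 0.397), with glgX (3.36 ± 0.18, adjusted p = 1.33e-10) and cspD (3.16 ± 0.31, adjusted p = 8.15e-08) higher. Polyhydroxyalkanoate metabolism gave 2 members higher and 1 lower of 4 tested (camera adjusted p = 0.661), with phaK (2.40 ± 0.17, adjusted p = 1.64e-09) higher.

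The SOS list gave 7 members higher and 14 lower of 26 tested (camera adjusted p = 0.267). dinB (3.40 ± 0.23, adjusted p = 1.48e-09) and recA (1.03 ± 0.19, adjusted p = 0.000138) rose, and lexA-I (-1.14 ± 0.20, adjusted p = 5.3e-05), recN (-0.79 ± 0.15, adjusted p = 0.000185) and rdgC (-3.34 ± 0.21, adjusted p = 4.97e-10) fell. Of oxidative stress defence, 10 of 26 tested members were higher and 14 lower (camera adjusted p = 0.267), with trxB (-4.74 ± 0.16), sodB (-4.30 ± 0.35) and ahpC (-3.07 ± 0.39, adjusted p of each at most 4.47e-06) lower and katE (1.64 ± 0.31, adjusted p = 0.000171) higher. fur (0.62 ± 0.23, adjusted p = 0.0245) was higher with groups that overlapped, and did not pass without replicate 1 (adjusted p = 0.103) or 2 (0.107) of the control or replicate 2 of H-3 (0.164). Nor did it in a fit of all 30 libraries (0.0684) or without the PP_mr entries (0.0651). Pyoverdine synthesis gave 6 members higher and 4 lower of 16 tested (camera adjusted p = 0.393), with pvdA (2.57 ± 0.23, adjusted p = 3.78e-08) and pvdT (2.36 ± 0.17, adjusted p = 1.65e-09) higher. Of 5652 genes tested, 4255 passed, 2186 higher and 2069 lower. No alternative moved this count by more than 1.5 times, and replicate 3 of H-3, with 77% rRNA, was among those left out in turn.

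Fe-55 against its FeCl3 control on day 1 asked what the isotope does beyond stable FeCl3. Nearly every ribosomal protein gene was higher with Fe-55, with a median log2 fold change of 3.52, and so were the genes of ATP synthase (4.48). The glucose transporter genes gtsA (8.07 ± 0.24) and gtsB (7.14 ± 0.40, adjusted p of each at most 2.78e-09) rose. gtsA was also far lower with FeCl3 than without addition on this day, so most of its rise depends on the FeCl3 control. Falls among genes with a symbol included those of the regulator gene exaE (-7.86 ± 0.60, adjusted p = 4.11e-08), the alcohol dehydrogenase gene qedH-II (-7.45 ± 0.50, adjusted p = 1.25e-08), the general stress gene csbD (-6.42 ± 0.39, adjusted p = 4.99e-09) and the acetoin dehydrogenase gene acoA (-6.03 ± 0.45, adjusted p = 3.04e-08). The catalase gene katE (-4.14 ± 0.20, adjusted p = 1.09e-09), the osmotic stress gene osmC (-5.81 ± 0.36, adjusted p = 6.6e-09) and rpoS (-3.15 ± 0.31, adjusted p = 4.62e-07) fell. Against the culture without addition csbD was higher, and acoA, katE and osmC did not pass. The tmRNA share was 11.9 ± 2.15% with Fe-55 and 29.5 ± 5.94% in the FeCl3 libraries, which stand apart from the other groups of day 1.

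Of ribosomal proteins, 52 of 54 tested members were higher and 1 lower (camera adjusted p = 7.92e-14 and 0.408). Of ATP synthase, 9 of 9 tested members were higher and none lower (camera adjusted p = 0.000131 and 0.407). Of glucose uptake and catabolism, 23 of 32 tested members were higher and 5 lower (camera adjusted p = 3.89e-07 and 0.264). Of the respiratory chain, 27 of 36 tested members were higher and 3 lower, 27 and 5 over the list alone (camera adjusted p = 5.17e-05 and 0.425). Of sulfur assimilation, 17 of 30 tested members were higher and 6 lower (camera adjusted p = 0.0223 and 0.408), with cysI (3.97 ± 0.24, adjusted p = 4.41e-09) higher. Of biofilm and exopolysaccharide, 23 of 28 tested members were lower and none higher (camera adjusted p = 0.00657 and 0.264), with the alginate regulator genes algR (-3.84 ± 0.36) and algB (-2.66 ± 0.18, adjusted p of each at most 2.95e-07) lower. Of prophages, 6 of 185 tested members were higher and 126 lower (camera adjusted p = 0.000116 and 0.467), as for PP_3851 (-2.92 ± 0.22) and PP_1579 (-2.65 ± 0.17, adjusted p of each at most 2.9e-08). Of pyoverdine synthesis, 1 of 16 tested members were higher and 13 lower (camera adjusted p = 0.000875 and 0.198), with pvdA (-3.45 ± 0.18, adjusted p = 1.43e-09) lower. Of the SOS list, 22 of 26 tested members were higher and 2 lower (camera adjusted p = 9.75e-05 and 0.36), with recA (2.09 ± 0.20, adjusted p = 2.82e-07), recN (1.39 ± 0.17, adjusted p = 3.12e-06), lexA-I (0.95 ± 0.14, adjusted p = 2.31e-05) and sbcD (3.75 ± 0.16, adjusted p = 4.75e-10) higher. sodB (2.74 ± 0.22, adjusted p = 7.1e-08) and ahpC (1.31 ± 0.20, adjusted p = 3.9e-05) were higher. fur (0.31 ± 0.17, adjusted p = 0.101) did not pass, but did with RLE (adjusted p = 0.0336) and DESeq2 (0.0172).

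In all 4360 of 5647 genes passed, 2024 higher and 2336 lower. Against the culture without addition, 1975 passed, 1040 higher and 935 lower. In that comparison, ribosomal proteins gave 10 members higher and 0 lower of 54 tested, 6 and 0 over the list alone (camera adjusted p = 0.074) and ATP synthase a camera adjusted p of 0.993. Glucose uptake and catabolism gave 12 members higher and 5 lower of 32 tested, 15 and 5 over the list alone (camera adjusted p = 0.429), the respiratory chain 4 members higher and 4 lower of 36 tested (camera adjusted p = 0.978), sulfur assimilation 5 members higher and 4 lower of 30 tested (camera adjusted p = 0.963) and biofilm and exopolysaccharide 3 members higher and 5 lower of 28 tested, 3 and 4 over the list alone (camera adjusted p = 0.676). The sign turned for csbD (0.89 ± 0.31, adjusted p = 0.0399), which passed, and for katE (0.47 ± 0.18, adjusted p = 0.054), osmC (0.14 ± 0.31, adjusted p = 0.769), algR (0.13 ± 0.32, adjusted p = 0.78) and ahpC (-0.35 ± 0.20, adjusted p = 0.194), which did not. The direction was kept but the call was lost for acoA (-0.56 ± 0.41, adjusted p = 0.319), algB (-0.27 ± 0.17, adjusted p = 0.248), cysI (0.39 ± 0.21, adjusted p = 0.172), sodB (0.53 ± 0.21, adjusted p = 0.0663) and PP_3851 (-0.17 ± 0.21, adjusted p = 0.572). Those changes thus depend on which control is used. Prophages gave 4 members higher and 63 lower of 185 tested (camera adjusted p = 1.12e-05 and 0.478) and pyoverdine synthesis 0 members higher and 16 lower of 16 tested (camera adjusted p = 2.35e-68 and 8.35e-07). Of the SOS list there, 12 of 26 tested members were higher and none lower (camera adjusted p = 0.000713 and 0.429).

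Fe-55 against FeCl3 on day 15 asked the same of old cultures. In the list of SOS response and recombination, which holds general recombination genes too, 19 of 26 tested members were higher and none lower. The list member lexA-II stood at 446 ± 43.4 CPM with Fe-55 and 0.6 ± 0.479 CPM with FeCl3. It counts among the 19 but is not ranked, as it switches between replicates of 2 groups of day 1. Of the others, the largest rises were those of the recombinase regulator gene recX (3.90 ± 0.16, adjusted p = 7.82e-11), the repair gene recN (3.63 ± 0.17, adjusted p = 1.81e-10), the recombinase gene recA (2.94 ± 0.21, adjusted p = 3.67e-08) and the repressor gene lexA-I (2.82 ± 0.20, adjusted p = 4.47e-08). The abundance of recA was 3001 ± 241 CPM with Fe-55, 372 ± 104 CPM with FeCl3, 393 ± 36.1 CPM without addition, 432 ± 16.1 CPM with Pu-239 and 706 ± 32.3 CPM with H-3. The manganese superoxide dismutase gene sodA (-5.80 ± 0.26, adjusted p = 1.76e-10) and the iron-free fumarase gene fumC-I (-5.97 ± 0.25, adjusted p = 9.69e-11) fell, and the iron superoxide dismutase gene sodB (2.27 ± 0.32, adjusted p = 5.42e-05) rose. Iron uptake genes such as fecI (-3.94 ± 0.31, adjusted p = 1.36e-07) and exbD (-3.47 ± 0.25, adjusted p = 5.06e-08) fell. ilvC (3.19 ± 0.31, adjusted p = 1.33e-06), of valine and isoleucine synthesis, rose. Of these, sodB and fecI did not pass against the culture without addition.

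In the SOS list, 19 of 26 tested members were higher and none lower (camera adjusted p = 1.32e-12 and 0.0385). Of ribosomal proteins, 35 of 54 tested members were higher and 1 lower, 36 and 1 over the list alone (camera adjusted p = 9.3e-08 and 0.729), among them rpmH (2.88 ± 0.27, adjusted p = 7.38e-07). Of flagella and chemotaxis, 24 of 46 tested members were higher and 1 lower, 24 and 2 over the list alone (camera adjusted p = 0.000812 and 0.729), with flgJ (2.13 ± 0.25) and fliG (1.80 ± 0.29, adjusted p of each at most 0.000143) higher. Of amino acid catabolism, 1 of 45 tested members were higher and 22 lower, 1 and 23 over the list alone (camera adjusted p = 0.000524 and 0.634), with the tyrosine and phenylalanine genes hpd (-2.99 ± 0.28) and hmgA (-3.22 ± 0.36, adjusted p of each at most 8.14e-06) lower. Of iron uptake and storage, 2 of 11 tested members were higher and 7 lower (camera adjusted p = 0.0071 and 0.634), where the bacterioferritin gene bfr-II (2.29 ± 0.23, adjusted p = 1.29e-06) was among those higher. Excision and mismatch repair gave 9 members higher and 3 lower of 20 tested (camera adjusted p = 0.205): uvrB (1.41 ± 0.18), alkB (1.67 ± 0.24) and uvrD (1.11 ± 0.19, adjusted p of each at most 0.000208) rose and uvrA (-1.47 ± 0.21, adjusted p = 5.67e-05) fell. Prophage genes gave 24 members higher and 54 lower of 184 tested, 23 and 51 over the list alone (camera adjusted p = 0.17), with PP_3901 (3.38 ± 0.28) and PP_3902 (2.85 ± 0.39, adjusted p of each at most 3.59e-05) higher. katE (-2.12 ± 0.32, adjusted p = 8.61e-05) was lower, and ahpC (-0.14 ± 0.37, adjusted p = 0.786), fur (-0.31 ± 0.23, adjusted p = 0.284) and rpoS (-0.35 ± 0.24, adjusted p = 0.245) did not pass, except fur without replicate 2 of FeCl3 (adjusted p = 0.0411).

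In all 2796 of 5652 genes passed, 1371 higher and 1425 lower. Against the culture without addition 3679 passed, and there the SOS list gave 11 members higher and 12 lower of 26 tested (camera adjusted p = 0.251), so the list did not rise as a whole against that control. Against H-3 it gave 16 members higher and 3 lower of 26 tested (camera adjusted p = 0.000146 and 0.628), a comparison chosen after seeing the data. Against no addition recX (3.20 ± 0.15), recA (3.06 ± 0.21), recN (2.87 ± 0.16) and lexA-I (2.51 ± 0.20) were higher with Fe-55, while rdgC (-1.47 ± 0.19), ruvA (-1.44 ± 0.16) and recJ (-0.79 ± 0.21) were lower, each with an adjusted p of at most 0.00289. Ribosomal proteins went the other way there, with 1 members higher and 52 lower of 54 tested (camera adjusted p = 2.76e-11 and 0.47), and rpmH (-2.89 ± 0.26, adjusted p = 7.91e-08) was lower. The sign also turned for katE (0.82 ± 0.31, adjusted p = 0.0271), which passed, and sodB (-0.20 ± 0.30, adjusted p = 0.574), which did not. The calls of fecI (-0.57 ± 0.28, adjusted p = 0.0857), flgJ (0.39 ± 0.24, adjusted p = 0.164), hpd (-0.36 ± 0.26, adjusted p = 0.222) and uvrD (0.41 ± 0.18, adjusted p = 0.0613) were lost. Against no addition ahpC (-3.82 ± 0.40, adjusted p = 1.29e-06) was lower, and rpoS (2.34 ± 0.25, adjusted p = 6.67e-07) and fur (0.79 ± 0.23, adjusted p = 0.00763) were higher. Flagella and chemotaxis gave 18 members higher and 8 lower of 46 tested, 17 and 8 over the list alone (camera adjusted p = 0.858) and iron uptake and storage 3 members higher and 4 lower of 11 tested (camera adjusted p = 0.394), while amino acid catabolism gave 11 members higher and 27 lower of 45 tested (camera adjusted p = 2.43e-05 and 0.166). Prophages turned, with 80 members higher and 16 lower of 184 tested, 80 and 15 over the list alone (camera adjusted p = 0.0127 and 0.709), and excision and mismatch repair gave 4 members higher and 6 lower of 20 tested (camera adjusted p = 0.951). The Fe-55 libraries are shared by both comparisons.

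**Figure D4:**
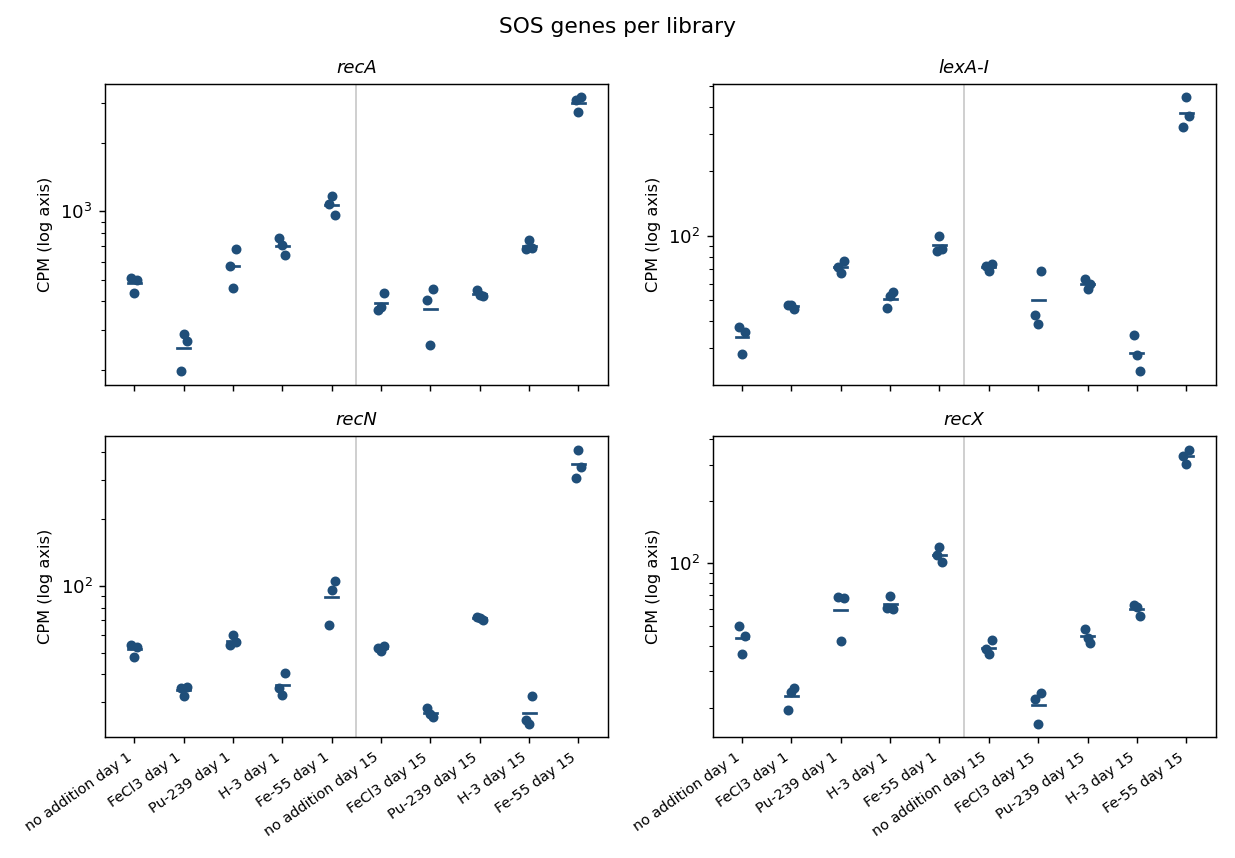
Abundance of the SOS genes recA, lexA-I, recN and recX in CPM on a log axis, with one point per library and a bar for the mean of each group. recA lies between 2727.1 and 3179.6 CPM with Fe-55 on day 15 and between 196.7 and 1164.2 CPM in all other libraries, and the lowest Fe-55 day 15 library is above all others for each of the 4 genes.

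FeCl3 against the culture without addition on day 1 compared 2 groups without radiation. Whether added iron, growth state or a batch sets them apart is left open here. The FeCl3 cultures had far lower levels of genes for protein synthesis and energy, with a median log2 fold change of -3.35 for ribosomal proteins and -4.72 for ATP synthase. Among genes with a symbol, large falls were those of gtsA (-7.15 ± 0.23, adjusted p = 1.42e-10), hutU (-6.54 ± 0.47, adjusted p = 2.87e-08), the glutamate transporter gene gltP (-6.41 ± 0.30, adjusted p = 1.2e-09) and the proline dehydrogenase gene putA (-6.37 ± 0.56, adjusted p = 2.17e-07). Large rises were those of the stress genes csbD (7.31 ± 0.41) and osmC (5.95 ± 0.37, adjusted p of each at most 8.7e-09), ldh (6.13 ± 0.33, adjusted p = 2.8e-09) and yohC (5.76 ± 0.41, adjusted p = 3.15e-08). The pyoverdine genes were lower, as for pvdQ (-3.54 ± 0.21) and pvdN (-3.45 ± 0.20, adjusted p of each at most 5.68e-09). The 3 FeCl3 libraries of this day stand apart from all other groups of day 1, with the tmRNA share at 29.5 ± 5.94%.

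Of ribosomal proteins, 1 of 54 tested members were higher and 52 lower (camera adjusted p = 1.4e-13 and 0.413). Of ATP synthase, 9 of 9 tested members were lower and none higher (camera adjusted p = 2.98e-05 and 0.413). Of glucose uptake and catabolism, 3 of 32 tested members were higher and 25 lower, 4 and 25 over the list alone (camera adjusted p = 7.5e-09 and 0.246). Of pyoverdine synthesis, 15 of 16 tested members were lower and none higher (camera adjusted p = 4.62e-08 and 0.01). Of the SOS list, 2 of 26 tested members were higher and 18 lower (camera adjusted p = 0.00889 and 0.482). Of flagella and chemotaxis, 22 of 46 tested members were higher and 4 lower (camera adjusted p = 0.00703 and 0.519), with flgA (2.55 ± 0.16) and fleS (2.49 ± 0.17, adjusted p of each at most 2.25e-08) higher. Of biofilm and exopolysaccharide, 15 of 28 tested members were higher and none lower (camera adjusted p = 0.00732 and 0.299). Of prophages, 69 of 185 tested members were higher and 13 lower, 59 and 11 over the list alone (camera adjusted p = 0.0296 and 0.65). In all 3891 of 5647 genes passed, 1909 higher and 1982 lower.

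FeCl3 against control on day 15 gave lower protein synthesis and energy genes as well, with medians of -2.74 for ribosomal proteins and -4.13 for ATP synthase. hutU (-7.17 ± 0.37, adjusted p = 2.38e-10), the thiolase gene bktB (-6.79 ± 0.30, adjusted p = 7.8e-11), gtsA (-6.68 ± 0.33, adjusted p = 1.85e-10) and rpmH (-5.77 ± 0.30, adjusted p = 2.29e-10) fell, and qmcA (5.81 ± 0.40), csbD (5.76 ± 0.33) and yohC (5.42 ± 0.35, adjusted p of each at most 3.31e-09) rose. The hibernation genes rmf (3.74 ± 0.29) and hpf (3.69 ± 0.25, adjusted p of each at most 9.73e-09) and rpoS (2.69 ± 0.26, adjusted p = 1.02e-07) rose. So did fecI (3.37 ± 0.30, adjusted p = 5.61e-08) and fpvA (1.56 ± 0.17, adjusted p = 4.4e-07). Of ribosomal proteins, 1 of 54 tested members were higher and 52 lower (camera adjusted p = 3.18e-17 and 0.322). Of ATP synthase, 9 of 9 tested members were lower and none higher (camera adjusted p = 1.39e-11 and 0.06). Of glucose uptake and catabolism, 3 of 32 tested members were higher and 23 lower (camera adjusted p = 4.01e-08 and 0.06). Of chaperones and proteases, 3 of 21 tested members were higher and 17 lower (camera adjusted p = 5e-09 and 0.16), with groS (-5.42 ± 0.19) and dnaK (-4.74 ± 0.19, adjusted p of each at most 3.13e-11) lower. Of prophages, 104 of 184 tested members were higher and 9 lower (camera adjusted p = 0.00186 and 0.604), as for PP_2270 (2.51 ± 0.22, adjusted p = 4.61e-08). In all 4095 of 5652 genes passed, 2229 higher and 1866 lower.

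Pu-239 against H-3 compared 2 sources at the same dose rate. On day 1 the genes with the smallest p were the aminotransferase gene aspC (4.62 ± 0.15, adjusted p = 1.92e-10) and the locus tags PP_3784 (6.89 ± 0.27), PP_3788 (4.76 ± 0.17) and PP_3790 (3.57 ± 0.14, adjusted p of each at most 9.28e-10), all higher with Pu-239. PP_3784 stood at 1021 ± 189 CPM with Pu-239, 8.71 ± 1.05 CPM with H-3 and 15.4 ± 2.15 CPM in the control. Of flagella and chemotaxis, 2 of 46 tested members were higher and 35 lower, 2 and 39 over the list alone (camera adjusted p = 5.85e-32 and 0.0768). Of chaperones and proteases, 10 of 21 tested members were higher and none lower, 11 and 2 over the list alone (camera adjusted p = 7.29e-06 and 0.715). Of pyoverdine synthesis, 1 of 16 tested members were higher and 1 lower, 1 and 0 over the list alone (camera adjusted p = 0.981), with a median of -0.003 and a mean of 0.029. In all 1745 of 5647 genes passed, 888 higher and 857 lower.

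On day 15 the thioredoxin reductase gene trxB (5.18 ± 0.17, adjusted p = 4.03e-12), the chaperonin gene groS (5.74 ± 0.19, adjusted p = 4.92e-12) and the lytic transglycosylase gene mltD (4.51 ± 0.18, adjusted p = 5.21e-11) were higher with Pu-239 than with H-3 and pqiA (-4.72 ± 0.19, adjusted p = 5.21e-11) was lower. Of ribosomal proteins, 52 of 54 tested members were higher and 1 lower (camera adjusted p = 2.36e-22 and 0.503). Of ATP synthase, 9 of 9 tested members were higher and none lower (camera adjusted p = 1.1e-05 and 0.503). Of prophages, 18 of 184 tested members were higher and 85 lower, 16 and 83 over the list alone (camera adjusted p = 0.00972 and 0.592). In all 4302 of 5652 genes passed, 2098 higher and 2204 lower. The tmRNA share was 15.9 ± 1.70% with Pu-239 and 44.3 ± 4.25% with H-3 on this day. These groups lie in different sets on the first principal component.

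Day 15 was compared with day 1 in the cultures without addition and with FeCl3. Without addition, old cultures had lower pyoverdine genes, as for pvdL (-2.30 ± 0.18) and pvdJ (-2.76 ± 0.22, adjusted p of each at most 3.8e-10), lower arginine deiminase genes, arcB (-4.06 ± 0.32) and arcC (-3.85 ± 0.29, adjusted p of each at most 3.05e-10). They had less of the flagellin gene fliC (-3.51 ± 0.29, adjusted p = 4.22e-10). mdh (5.24 ± 0.51, adjusted p = 9.33e-09) and the oxidase genes cioA (3.86 ± 0.28) and cioB (2.82 ± 0.26, adjusted p of each at most 2.75e-09) rose. So did chaperone genes such as hslU (1.90 ± 0.20) and dnaK (1.85 ± 0.20, adjusted p of each at most 6.82e-08). Of pyoverdine synthesis, 16 of 16 tested members were lower and none higher (camera adjusted p = 1.03e-18 and 0.000106). Of ribosomal proteins, 49 of 54 tested members were lower and none higher, 50 and 0 over the list alone (camera adjusted p = 2.61e-09 and 0.562). Of chaperones and proteases, 15 of 21 tested members were higher and 2 lower (camera adjusted p = 2.16e-06 and 0.397). Of the respiratory chain, 2 of 36 tested members were higher and 24 lower, 2 and 27 over the list alone (camera adjusted p = 3.16e-07 and 0.397). Of 5665 genes tested, 2642 passed, 1319 higher and 1323 lower.

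With FeCl3, whose libraries of day 1 stand apart from the other groups of that day, so that this comparison is not shown to be one of age alone, flagella and chemotaxis genes fell, among them the flagellin gene fliC (-5.59 ± 0.32, adjusted p = 5.69e-13) and the motor genes motA (-3.19 ± 0.19) and motB (-3.10 ± 0.17, adjusted p of each at most 2.06e-12), and the branched-chain catabolism gene bkdAB (2.84 ± 0.24, adjusted p = 6.19e-10) rose. Among flagella and chemotaxis genes, 1 of 46 tested members were higher and 44 lower (camera adjusted p = 1.27e-14 and 0.528). Of ribosomal proteins, 2 of 54 tested members were higher and 34 lower, 2 and 36 over the list alone (camera adjusted p = 0.0032 and 0.834). Of amino acid catabolism, 15 of 45 tested members were higher and 5 lower (camera adjusted p = 0.00402 and 0.834). Of the list of efflux pumps, 7 of 14 tested members were higher and 1 lower (camera adjusted p = 0.0395 and 0.834). Of 5665 genes tested, 2534 passed, 959 higher and 1575 lower.

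Whether an effect differed between day 15 and day 1 was tested directly. For Pu-239, 1395 of 5665 genes passed, 682 with a higher effect on day 15 and 713 with a lower one. The smallest p were those of PP_3784 (-6.33 ± 0.29), PP_3788 (-4.66 ± 0.21), aspC (-4.35 ± 0.20) and PP_3332 (-7.14 ± 0.37, adjusted p of each at most 1.48e-13), all lower in the difference. Of pyoverdine synthesis, 16 of 16 tested members were higher and none lower (camera adjusted p = 1.85e-41 and 4.38e-07). Of nitrogen limitation, 13 of 25 tested members were lower and none higher, 14 and 0 over the list alone (camera adjusted p = 0.000168 and 0.0178). Of the respiratory chain, 24 of 36 tested members were lower and none higher, 27 and 0 over the list alone (camera adjusted p = 1.31e-11 and 0.159). For H-3, 3812 passed, 1851 and 1961, with pvdT (5.02 ± 0.21), pvdA (7.16 ± 0.32) and PP_3314 (5.63 ± 0.26, adjusted p of each at most 1.27e-14) higher and gtsA (-7.59 ± 0.35, adjusted p = 1.36e-14) lower. There, of pyoverdine synthesis, 16 of 16 tested members were higher and none lower (camera adjusted p = 1.94e-15 and 0.00089), and of ribosomal proteins, 1 of 54 tested members were higher and 52 lower (camera adjusted p = 2.88e-23 and 0.355). Without the PP_mr entries in the scaling, 2061 genes had a higher H-3 effect on day 15 and 1774 a lower one, so this balance rests on the scaling. For Fe-55, 3446 passed, 1807 and 1639, with gtsA (-9.05 ± 0.37), sdaC (-6.79 ± 0.30) and yihS (-6.24 ± 0.28, adjusted p of each at most 5.59e-15) lower and PP_3267 (4.76 ± 0.25, adjusted p = 1.68e-13) higher. Of ribosomal proteins in that difference, 52 of 54 tested members were lower and none higher (camera adjusted p = 1.62e-11 and 0.382). The control of day 1 had the highest pyoverdine levels of its day, and it enters the Pu-239 and H-3 differences with its sign reversed.

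Differences between sources set each radionuclide against its own control. On day 1, the Fe-55 effect minus the Pu-239 effect passed in 3664 of 5647 genes, 1836 higher and 1828 lower. gtsA (7.90 ± 0.28, adjusted p = 5.42e-10) was higher, and aspC (-5.25 ± 0.19, adjusted p = 5.42e-10), PP_0412 (-11.63 ± 0.44, adjusted p = 6.84e-10) and PP_0411 (-12.07 ± 0.47, adjusted p = 7.88e-10) were lower. FeCl3 against no addition enters this difference with its sign reversed. gtsA was far lower in that comparison, so its value here rests largely on the FeCl3 control. With no addition as the control for both on that day, fewer genes passed. PP_0412 stood at 8225 ± 1775 CPM with FeCl3, 881 ± 164 CPM with Pu-239 and 45.8 ± 11.8 CPM in the control. On day 15, 2049 of 5652 passed, 972 higher and 1077 lower, and without the PP_mr entries in the scaling 1105 were higher and 816 lower. fumC-I (-7.93 ± 0.33) and PP_0945 (-6.56 ± 0.28, adjusted p of each at most 1.61e-10) were lower. Of the SOS list in that difference, 13 of 26 tested members were higher and none lower (camera adjusted p = 1.87e-09 and 0.123). Of ribosomal proteins there, 41 of 54 tested members were higher and none lower, 45 and 0 over the list alone (camera adjusted p = 2.57e-13 and 0.497). Without the PP_mr entries these lists had 14 higher and 0 lower, and 42 higher and 0 lower. Against the culture without addition, Fe-55 on day 15 had 11 SOS members higher and 12 lower, and 1 ribosomal protein gene higher and 52 lower. The median change of ribosomal proteins was -1.81 there, and -0.563 for Pu-239 without the PP_mr entries. Their rise in this difference thus depends on FeCl3 as the control.

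The Fe-55 effect minus the H-3 effect passed on day 1 in 3372 of 5647 genes, 1725 higher and 1647 lower, with gtsA (7.51 ± 0.27, adjusted p = 1.27e-09) higher and pfpI (-5.54 ± 0.23), PP_3267 (-5.34 ± 0.23) and PP_0903 (-4.87 ± 0.21, adjusted p of each at most 2.95e-09) lower. With the culture without addition as control for both, which leaves Fe-55 against H-3 directly, 10 genes passed and 419 had an unadjusted p under 0.05. These 10 were chosen after their values were seen. The genes gtsA (0.36, adjusted p = 0.67), pfpI (-0.31, 0.67), PP_3267 (-0.075, 0.99) and PP_0903 (-0.62, 0.153) did not pass with that control. With Fe-55 the genes recN (1.31 ± 0.17), lexA-I (0.83 ± 0.14) and PP_0099 (1.93 ± 0.20) were higher, as were PP_4616, PP_0023, PP_2109, PP_3773, PP_3901 and PP_0682, and nuoN (-2.12 ± 0.37) was lower, each with an adjusted p of at most 0.0425. The number of calls depends on the model: with pair terms by replicate number, the fit of 15 libraries called 39 genes, these 10 among them. A fit of the 6 libraries with pair terms called 0. No fit of the 6 without pair terms was made, so that loss is not shown to come from pairing. On day 15 the difference of effects passed in 4145 of 5652, 1928 higher and 2217 lower, with trxB (5.55 ± 0.21), rpmG (7.68 ± 0.29), groS (6.22 ± 0.25) and cyoC (6.58 ± 0.27, adjusted p of each at most 3.62e-11) higher. Fe-55 against H-3 directly gave 3282. Of ribosomal proteins in the day 15 difference, 52 of 54 tested members were higher and 1 lower (camera adjusted p = 1.31e-31 and 0.237). In the SOS list there, 18 of 26 tested members were higher and 2 lower (camera adjusted p = 7.33e-05 and 0.237).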

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

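The counts over other splits of the libraries, the correlation of the FeCl3 libraries with other groups, the test of stable iron and the 3 tests on SOS genes were chosen only after the result was seen. Effects that differed by a direct test of the difference were those of Pu-239 (1395 genes), H-3 (3812) and Fe-55 (3446) between day 15 and day 1. The Fe-55 effect differed from the Pu-239 effect in 3664 genes on day 1 and 2049 on day 15, and from the H-3 effect in 3372 and 4145. tmRNA is in no comparison, and its share of the counts outside rRNA lay above every library without addition of the same day with H-3 on day 15 (44.3%), with Fe-55 on day 1 (11.9%) and day 15 (42.9%), and with FeCl3 on day 1 (29.5%) and day 15 (47.6%). With Fe-55 it was lower than with FeCl3 on day 1.

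The 6 libraries of a pair of groups make 10 splits, too few for a share under 0.05. In each pair 1 split, the real one, gave as many genes. Real and highest other counts were 1375 and 1 for Pu-239 on day 1, 988 and 2 on day 15, 1801 and 1 for H-3 on day 1, and 4255 and 0 on day 15. For Fe-55 against FeCl3 they were 4360 and 0, and 2796 and 0, and for FeCl3 against no addition 3891 and 0, and 4095 and 1. For Pu-239 against H-3 they were 1745 and 1, and 4302 and 0, and for time 2642 and 1 without addition and 2534 and 1009 with FeCl3. For the differences of effects, 100 splits were drawn with a fixed seed. The real one alone gave as many for Pu-239 (1 split, highest other 1155) and H-3 (1 split, 3664) between days, and for Fe-55 minus H-3 on day 15 (1 split, 3825). For Fe-55 minus Pu-239, 2 splits did on day 1 (highest other 4074) and 2 on day 15 (2252). For Fe-55 between days 6 splits did (highest other 4353), and for Fe-55 minus H-3 on day 1 it was 5 splits (4259). Every other split that gave as many kept 1 treated group and its control whole, as labelled or exchanged, so it held a real difference. Of the 85 that broke both, the highest count was 116, for Fe-55 between days, and 0 or 1 for the others. Those 85 mix libraries of unlike groups, which widens the spread within a group, so low counts were built in. The splits therefore do not decide for any of these differences whether a random split is excluded.

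The FeCl3 libraries of day 1 stood apart from all other libraries of that day. Their highest correlation with a library of another group was 0.866, below the lowest within any group, 0.903. This argues against single libraries or further libraries of another of the 10 groups. An exchange of labels between whole groups would leave these values the same and cannot be told apart. Stable iron cannot be told apart: over 2942 genes that FeCl3 changed at least 2-fold (median 1.96), Fe-55 against H-3 moved by a median of -0.051 in the FeCl3 direction (quartiles -0.228 and 0.118), but no table gives the iron in the Fe-55 cultures, and the labels call FeCl3 equimolar without a value for them. A later growth state also stays open as a candidate explanation: the FeCl3 change correlated with the change of H-3 cultures from day 1 to day 15 at r = 0.664 over 5646 genes, and of the genes FeCl3 changed at least 2-fold, 87.7% went the same way. The same correlation was 0.72 with Fe-55 and 0.371 with Pu-239, and a batch of cultures or libraries shared by this group was not testable.

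Of the list of SOS response and recombination, 19 members were higher with Fe-55 than with FeCl3 on day 15. Scaling, which moves every gene alike, is argued against for the list as a whole, since the median of its 26 tested members lay 0.76 above the median of all genes (quartiles 0.246 and 2.38), though not for members with small changes. A low level in FeCl3 cannot be told apart from a rise with Fe-55 for the whole set, as 10 of the 19 were also higher against no addition and 8 lower. Neither can the state of old cultures, as 12 were higher than with H-3 and 3 lower. For the 7 members higher in all 3 comparisons, which share the Fe-55 libraries and include the switching gene lexA-II, a response to Fe-55 stays open.

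H-3 and Fe-55 libraries of day 1 deviated together by replicate number. The deposit of 1 library under 2 names is argued against by a chi-square per gene of 144.91 in the closest of the 3 pairs (145.18 and 247.95 in the others). Shared handling of cultures with the same number cannot be told apart from other causes: over 75 tRNA entries the lowest of the 3 correlations was 0.286 (0.461 and 0.304 in the others, -0.167 on average for other numbers), between the bounds set beforehand. No biological explanation was tested.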

How the results depend on the processing

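Leaving out the libraries over 30% rRNA, the PP_mr entries or the switching genes, and the culture without addition as control in the differences of Fe-55, and a replicate block in Fe-55 against H-3, were tests chosen only after the result was seen. All other alternatives were planned, and none was left unrun. Fits of the 6 libraries and of all 30 were planned and run for the 10 comparisons within a day only. Counts of genes stayed within 1.5 times under DESeq2, RLE scaling, no filter, structural RNA kept in, the replicate block and the 3 omissions above. With 1 replicate left out, that held for all comparisons but Pu-239 on day 15 (539 to 837, against 988). A minimum of 2-fold, which is stricter by construction, gave 757 genes for Pu-239 on day 1, 311 on day 15, 800 for H-3 on day 1, 1310 for Fe-55 on day 15, 914 for Pu-239 against H-3 on day 1, and for time 1333 without addition and 1339 with FeCl3. A fit of the 6 libraries gave 2105 and 2115 for Pu-239 on day 1 and 15, and a fit of all 30 gave 605 on day 15. The cause was not tested. With no addition as the control, Fe-55 on day 1 gave 1975, Fe-55 minus Pu-239 gave 1789 on day 1 and 3827 on day 15, and Fe-55 minus H-3 on day 1 gave 10. By construction these take FeCl3 out, and the differences within a day take no addition out as well, so the move follows FeCl3 against no addition. Which of the 2 groups accounts for it was not tested. With that control the signs reversed on day 1 for ahpC (-0.35), algR (0.13), csbD (0.89), katE (0.47) and osmC (0.14), and on day 15 for katE (0.82), rpmH (-2.89) and sodB (-0.20). Of these, csbD (adjusted p = 0.0399), katE on day 15 (0.0271) and rpmH (7.91e-08) passed in the new direction. For the others (0.054 to 0.78) no turn is shown.

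Of 475 tests of lists, 198 passed with the preset correlation, 8 with an estimated one and 337 with fry. Of the 249 results for genes named in the comparisons, 232 were called, and 202 of these kept call and direction in all alternatives but the 2-fold minimum. Over 4252 values, 4150 stayed, 81 lost and 11 gained a call, 8 reversed and 2 uncalled ones moved. Scaling moved the median of all genes by more than 0.1 in Fe-55 on day 1 (RLE 0.107, DESeq2 0.106), in Fe-55 between days (-0.11, -0.111) and in Fe-55 minus Pu-239 on day 1 (0.12, 0.117). Without PP_mr it moved for H-3 (0.206) and Fe-55 (0.111) between days, FeCl3 on day 15 (-0.1), and on day 15 Fe-55 minus Pu-239 (0.141) and minus H-3 (0.138). Structural RNA kept in moved it for time with FeCl3 (0.104). Small changes can be missed. In simulated counts 49% of 2-fold changes were called for Pu-239 on day 1, 69% on day 15, and 24% for Fe-55 minus Pu-239 on day 15.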

Other observations

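All tests in this part were chosen only after the result was seen. The comparisons fixed beforehand did not include the days within a radionuclide, and these values come from the fit of all 30 libraries. From day 1 to day 15, 3448 of 5665 genes passed with Pu-239 (1776 higher, 1672 lower), 4464 with H-3 (2235 and 2229) and 4236 with Fe-55 (2165 and 2071). With Pu-239 ribosomal proteins gave 0 members higher and 52 lower of 54 tested, 0 and 53 over the list alone (camera adjusted p = 7.75e-16 and 0.313). With H-3 they gave 0 members higher and 52 lower of 54 tested (camera adjusted p = 2.31e-21 and 0.306), and with Fe-55 1 members higher and 52 lower of 54 tested, 1 and 53 over the list alone (camera adjusted p = 8.11e-15 and 0.295). The siderophore gene pvdA (2.13 ± 0.21, adjusted p = 6.94e-09) was higher on day 15 with Pu-239, as were pvdA (4.97 ± 0.24, adjusted p = 2.01e-15) with H-3 and pvdA (3.01 ± 0.22, adjusted p = 7.29e-12) with Fe-55. The sigma factor gene rpoS (2.79 ± 0.29, adjusted p = 2.36e-09) was higher with H-3 and rpoS (3.32 ± 0.30, adjusted p = 2.53e-10) with Fe-55, and rpoS (-0.08 ± 0.27, adjusted p = 0.816) did not pass with Pu-239. With Pu-239, PP_3784 (-6.25 ± 0.23, adjusted p = 1.22e-16) and aspC (-3.91 ± 0.15, adjusted p = 2.81e-16) were lower.

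A hypothesis is that some genes may show a response to Fe-55 on both days. Of the 9 genes higher with Fe-55 than with H-3 on day 1, 7 were also higher with Fe-55 than with FeCl3 on day 15, in other libraries, against 24.3% of all genes tested (Fisher's exact p = 0.00109). That test takes genes as independent, but their day 15 values all come from the same libraries. Its p does not measure the spread between cultures. The 7 are those other than PP_0023 and PP_0682, recN and lexA-I among them. Of the 7, PP_3901 did not pass against the culture without addition on day 1 (-0.17, adjusted p = 0.663), and the other 6 were higher. The set is small and depends on the model: with terms for pairs of the same number, the fit of 15 libraries gave 39 genes, 17 higher and 22 lower, which held all 10 calls, and 9 of the 17 were higher on day 15. A paired edgeR fit of the 6 libraries called 0, with 942 at an unadjusted p under 0.05. Libraries that share a number may share handling, so these genes are a lead for new cultures rather than a measured effect.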
